A study of Cupriavidus metallidurans CH34 with 24 samples.

How the data were processed

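Transcript signals were measured in 24 samples of C. metallidurans CH34 on single-colour Agilent arrays, in 10 groups of which 7 had 3 arrays and 3 had 1 array. Per the labels, RNA was purified on columns with DNase digestion, its integrity was checked, and labelling was done by 1 of 2 service providers without saying which samples went to which. The scanner files split the arrays into 2 series with Agilent Feature Extraction 10.7.3.1 (9 arrays) and 10.5.1.1 (15 arrays). Per the file headers, the processed signal is a linear intensity from which the software subtracted background, removed spatial and multiplicative trends and replaced small values, without normalization between arrays. The deposited mean signal and local background columns are pixel intensity values, and the flags for well above background, saturation and outlier spots are other values of 0 or 1. The authors' value table is a linear intensity of 9735 lines per array, scaled so that each column sums to about 10000, by a method that is not stated.

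Each array carried 15207 probes, with 1 spot per probe and the same sequence under each probe name in both series: 9843 probes for genes and 5364 for intergenic regions. The files of the second series hold no gene names, so names were taken from the first series through the probe name. They give 6681 gene names, of which 6352 are locus tags and 329 are symbols; 3519 had 1 probe and 3162 had 2. The files do not pair locus tags with product names, and no annotation was at hand. Names for the regions cop, cup, gig, cus, cop2, sil and czc come from prior knowledge of the strain's annotation and were fixed with the other choices at the start.

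The log2 processed signal of each array was centred on its 75th percentile over all probes, and spots with an outlier flag were left out. Probes were averaged per gene, and a gene was kept if a probe was well above background on at least 3 arrays of the fit. The array count limits the precision. Comparisons within the first series and within the second series were each fitted together in limma 3.58.1 (lmFit and eBayes with a trend, two-sided) in R 4.3.3, with 6 and 8 residual degrees of freedom. Comparisons across the series used a fit over all 24 arrays with 14 residual degrees of freedom. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each comparison. Groups with 1 array entered the fit under the assumption that they vary like the other groups; the 500 µM AuCN and KCN arrays were compared as values only, for genes well above background on both and at least 4-fold apart. The comparisons were Au-malate and Au-thiosulfate each with untreated cells and with each other, AuCN with KCN at 50 µM and at 5 mM, the higher with the lower dose of each, the interaction, AuCl4 with KCN and AuCN at 50 µM, and the 4 AuCN and KCN groups with untreated cells. A change was given as at least N-fold, with the dim group's values raised at least to the lowest signal called well above background on each array, where the lower group was not well above background on every array, and without a fold where neither group had an array that was. This wider use for groups with some arrays well above background was added after the data had been seen.

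Gene lists were tested with camera, a competitive set test in limma, at a preset correlation between genes of 0.01 and adjusted over the 11 lists with at least 3 members in each comparison. The estimated correlation was used as an alternative. The lists were cop (19 genes), cup (3), gig (4), cus (5), cop2 (6), sil (4), czc (16), heat shock and proteases (6), ribosomal proteins (47), flagellum and chemotaxis (20) and TCA cycle (7). Lists with fewer than 3 members were not tested as sets: iron-sulfur assembly (hscA, hscB), sulfate assimilation (cysM), ATP synthase (atpC) and phosphate (pstA, pstC). Lists with 0 members under the names the files give were mer, ars, pbr, cnr and chr, zinc uptake, oxidative and thiol stress, siderophore and iron, sox, terminal oxidases, nuo, transport RND, sigma factors, hydrogenase and CO2 fixation, rhodanese and cyanate, mobile elements, and Entner-Doudoroff. The median of a list at 500 µM was ranked among 10000 random lists of the same size, matched on mean signal of the arrays compared.

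Named genes were chosen by a rule written at the start. It took the 8 largest rises and 8 largest falls of each comparison among genes past the threshold that changed at least 2-fold with groups that did not overlap, or 4 and 4 for the interaction, comparisons with a lone array and those across series. It added up to 2 risen and 2 fallen genes per list, and the cup and gig genes, copA and copB whatever their values. Runs of neighbouring locus tags were added after their values were seen.

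Alternatives chosen before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization, centring on the median, no filter, the brightest probe per gene, the authors' value table, a fit over all 24 arrays or over only the 2 groups compared, a replicate block, a slide block, and leaving out each replicate in turn. After the data had been seen, 5 more were added: genes well above background on every array compared, a fit without the 5 mM and 500 µM KCN arrays, the arrays of slide 3 or slide 4 only, scaling to the spike-in probes, and centring the 5 mM arrays on genes well above background on all of them. Other splits of the samples were counted, all of them up to 100. Samples were not treated as paired by replicate number. After group means were removed, arrays with the same number correlated by -0.185 to 0.515 in the first series, by 0.119 to 0.326 between Au-malate and Au-thiosulfate, and by -0.250 to 0.171 in the second. Between Au-malate and Au-thiosulfate, arrays with different numbers correlated by at most -0.003. Between untreated and Au-malate they reached 0.031, where the same number gave 0.051 to 0.515. Between untreated and Au-thiosulfate they reached 0.170, where the same number gave -0.185 to 0.212. Pairing in the first series was not ruled out, and the replicate block was its alternative.

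The procedure was tested on simulated data with 50 changed genes of each size. For Au-malate against untreated cells it called 94% of 2-fold and 98% of 4-fold changes, with 11 false calls among 190. For AuCN against KCN at 50 µM it called 68% and 94% (6 false of 147), and at 5 mM 62% and 98% (3 of 145). For the interaction it called 40% and 88% (8 of 121), and for AuCl4 against KCN 34% and 86% (8 of 119). For AuCN at 50 µM against untreated cells it called 70% and 100% (6 of 158). The noise was drawn independently for each gene on values already scaled, and few genes were changed. The scaling, dim spots, correlated genes, changes of many genes and a lone array with a wider spread were therefore not tested. The R packages data.table (1.17.8) and jsonlite (2.0.0) were used, and figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. The value table was left out of comparisons with the second series because many of its lines there did not match the scanner files.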

Results

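The study followed the transcripts of Cupriavidus metallidurans CH34, a metal-resistant bacterium, after contact with different chemical forms of gold. Cells grown in mineral salts medium with Na-gluconate received a gold species or potassium cyanide, or nothing, and total RNA was hybridised to 24 Agilent arrays in the Cy3 channel. 7 groups had 3 arrays each: untreated cells (10 min), 500 µM Au-malate (10 min), 500 µM Au-thiosulfate (10 min), 50 µM AuCN (10 min), 50 µM KCN (10 min), 5 mM AuCN (30 min) and 5 mM KCN (30 min). 3 conditions had 1 array each: 50 µM AuCl4 (10 min), 500 µM AuCN (30 min) and 500 µM KCN (30 min). The labels do not say that replicates came from separate cultures, so the p values measure only the spread between these samples, which may be technical.

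The untreated, Au-malate and Au-thiosulfate arrays formed a first array series of 9 arrays. The other 15 arrays formed a second series with another array design, other slides, other scans and another version of the scanner software. In the first series, 89.9% to 93.3% of probes were well above background. The share was 73.5% to 85.3% with 50 µM AuCN, 73.3% to 82.2% with 50 µM KCN and 68.9% to 75.6% with 5 mM AuCN. On the 5 mM KCN arrays it was 43.4% to 45.5%, and their 75th percentile of signal was 14.9 to 21.9 intensity units, against 46.5 to 49.1 with 5 mM AuCN and 58.8 to 92.0 with 50 µM KCN. The 10 brightest probes held 63.7% to 71.5% of the signal on the 5 mM KCN arrays and 8.61% to 13.8% in the first series. Log2 signals of replicates correlated across genes with r of 0.955 to 0.994, and genes are not independent replicates.

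**Figure D1:**
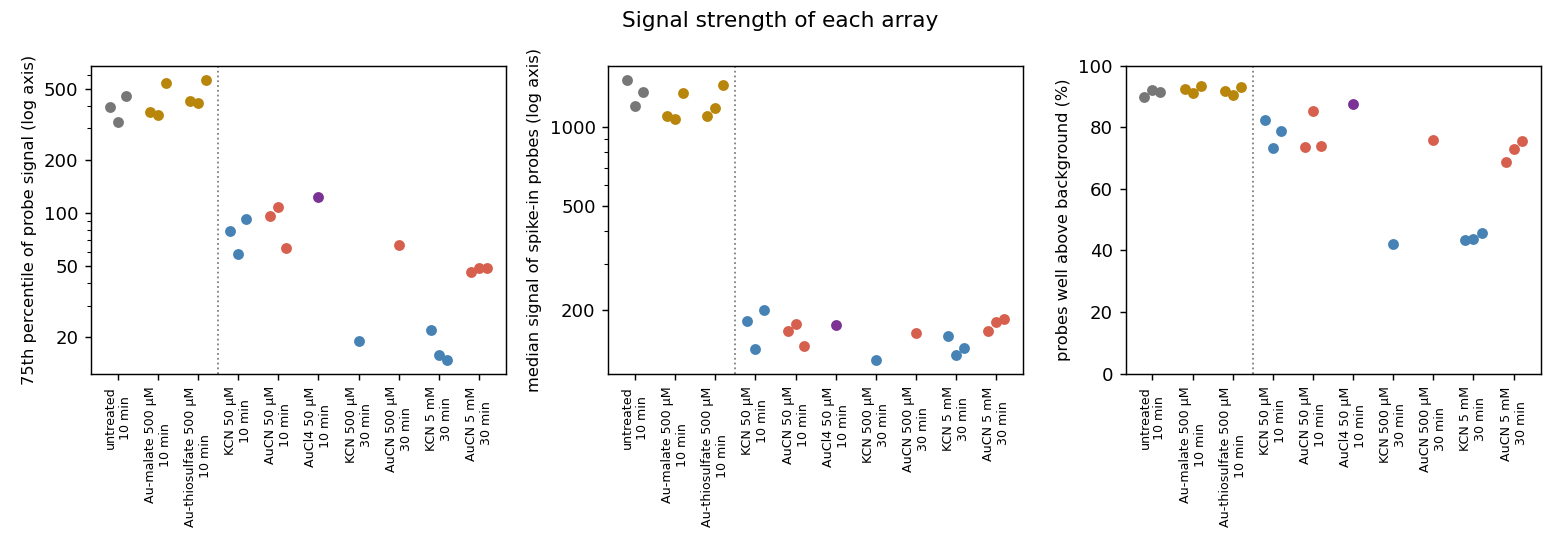
Signal of each array by group: 75th percentile of the probe signal (log axis, intensity units), median signal of the spike-in probes (log axis, intensity units) and percent of probes well above background. The 5 mM KCN arrays lie at 43.4% to 45.5% of probes and the 500 µM KCN array at 42.0%.

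Gold supplied as Au-malate changed few transcripts within 10 min. A run of 7 neighbouring genes fell together. Among genes that passed, 1 gene of the cus region, a copper and silver efflux region of the chromid, gave the largest rise. Its call ended without each untreated replicate. The cup genes, which encode a MerR-type regulator (cupR), a P-type ATPase (cupA) and a small copper chaperone (cupC), did not pass over all genes. The comparison with untreated cells asked which genes respond to gold complexed by malate, with 3 arrays in each group.

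Of 6464 genes tested, 62 changed (limma, adjusted p under 0.05), of which 32 rose and 30 fell. At least 2-fold, 3 rose and 13 fell, and 428 genes had an unadjusted p under 0.05. Genes Rmet_2811 to Rmet_2817 fell with a median of 3.52-fold, at most 4.05-fold, and a highest adjusted p of 0.00647; the files do not name their products. Outside this run, Rmet_4988 fell (log2 change -1.62, SE 0.18, adjusted p = 0.0031). Rmet_5034 of the cus region rose by a log2 change of 1.51 (SE 0.31, adjusted p = 0.0496), a call that also ended in the fit over all 24 arrays and without Au-malate replicates 1 and 3. Its neighbour Rmet_5035 rose by 1.34 (SE 0.25, adjusted p = 0.038), and Rmet_4889 rose 2.15-fold (SE 0.19 on the log2 scale, adjusted p = 0.021). The cup genes Rmet_3523, Rmet_3524 and Rmet_3525 (cupR, cupA, cupC) differed by 0.22, 0.30 and 0.47, with 95% intervals of -0.04 to 0.49, 0.10 to 0.51 and 0.17 to 0.78; none passed over all genes and 2 passed adjusted over the list alone. The copper-resistance genes copA (Rmet_6112) and copB (Rmet_6113) of plasmid pMOL30 differed by -0.02 each, with intervals of -0.27 to 0.23 and -0.30 to 0.26. The gig genes, named for induction by gold, differed by -0.07 to 0.25 for the 3 measured members, with no adjusted p below 0.95; Rmet_4684 was well above background on fewer than 3 arrays of each series, so the filter left it out of the tests within them.

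As sets, the cus region was higher with Au-malate (median log2 change 1.23, adjusted p = 0.00054; adjusted p = 0.20 with an estimated correlation), with 1 of 5 genes risen and 3 adjusted over the list alone. The cup set was higher (adjusted p = 0.00056; adjusted p = 0.096 with an estimated correlation), as was the sil region of pMOL30 (median 0.30, adjusted p = 0.0083; adjusted p = 0.13 with an estimated correlation), where Rmet_6135 rose by 0.71 (SE 0.14, adjusted p = 0.04). The 47 ribosomal protein genes were lower by a median of -0.23 (adjusted p = 1.4e-11; adjusted p = 0.35 with an estimated correlation) and none passed alone. Heat shock genes and flagellum genes were lower at an adjusted p of 0.045 each, which rose to 0.35 and 0.67 with an estimated correlation and to 0.053 and 0.052 with a slide block. The calls of Rmet_5034, Rmet_5035 and Rmet_6135 also ended with a slide block. In the first series this block sets apart only Au-thiosulfate replicate 1, the only array there on slide 2. The cop cluster (adjusted p = 0.52), gig (0.77), cop2 (0.29), czc (0.52) and the TCA cycle (0.42) did not pass. In one fit over all 24 arrays 31 genes changed, and 29, 32, 33 and 32 changed without Au-malate replicate 1 and untreated replicates 1, 2 and 3.

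No transcript passed the threshold with Au-thiosulfate. Gold complexed by thiosulfate was compared with untreated cells at the same dose and time as Au-malate, with 3 arrays in each group. By limma 0 of 6464 genes changed, and 692 had an unadjusted p under 0.05. The cupR, cupA and cupC genes differed by log2 changes of -0.15, 0.09 and -0.01, with 95% intervals of -0.41 to 0.12, -0.11 to 0.30 and -0.32 to 0.29. For copA and copB the intervals ran from -0.32 to 0.18 and from -0.48 to 0.08. Ribosomal protein genes were lower by a median of -0.22 (adjusted p = 1.1e-07; adjusted p = 0.93 with an estimated correlation). Flagellum genes were higher by a median of 0.12 (adjusted p = 0.0065; adjusted p = 0.93 with an estimated correlation), and TCA cycle genes were lower (adjusted p = 0.013; adjusted p = 0.93 with an estimated correlation) with 2 fallen adjusted over the list alone, and gave 0.055 with a slide block. No other list had an adjusted p below 0.66. Without Au-thiosulfate replicate 2 the count was 7 genes, and without untreated replicate 2 it was 1 gene.

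Set against each other at the same dose and time, the malate and thiosulfate complexes differed in the same run Rmet_2811 to Rmet_2817 and in the cus region. Of 6464 genes, 44 were higher and 25 lower with Au-malate (limma), 4 and 12 of them at least 2-fold, and 959 had an unadjusted p under 0.05. The run was lower with Au-malate by log2 changes of -1.58 to -1.76, and Rmet_4988 by -1.54 (SE 0.18). Rmet_5034 was higher by 1.64 (SE 0.31, adjusted p = 0.029), Rmet_5035 by 1.26 and Rmet_4889 by 1.25; the calls of Rmet_5034 and Rmet_5035 ended with a slide block. The cupR, cupA and cupC genes were higher by 0.37, 0.21 and 0.48 and passed only adjusted over the list alone, where all 3 did. As sets, cup (adjusted p = 0.0165; adjusted p = 0.23 with an estimated correlation), cus (adjusted p = 0.031; adjusted p = 0.59 with an estimated correlation) and sil (adjusted p = 0.031; adjusted p = 0.23 with an estimated correlation) were higher with Au-malate, the last 2 at an adjusted p of 0.056 with a replicate block. Flagellum genes were lower (median -0.17, adjusted p = 4.6e-05; adjusted p = 0.59 with an estimated correlation). The ribosomal protein genes gave an adjusted p of 0.92. The count was 35 genes in one fit over all 24 arrays, 33 with a slide block and 117 with a replicate block. It was 44, 33 and 26 without Au-malate replicate 1, Au-thiosulfate replicate 1 and Au-thiosulfate replicate 3. Because only Au-thiosulfate replicate 1 lay on slide 2, the slide block and leaving out that array are nearly the same check.

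AuCN at 50 µM raised the cup genes strongly over KCN at the same dose and time. Chaperonin and protease genes and 45 of 47 ribosomal protein genes were also higher than with KCN. So were 7 neighbouring genes of the cop cluster, Rmet_6117 to Rmet_6123, while copA and copB did not pass. Against untreated cells, in the other array series, the ribosomal median was -0.26 with AuCN and -1.12 with KCN. The AuCN and KCN groups received matched doses for 10 min, with 3 arrays in each group, to ask what the gold added. The labels do not give the free cyanide in either group, so a difference cannot be credited to gold alone.

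**Figure D2:**
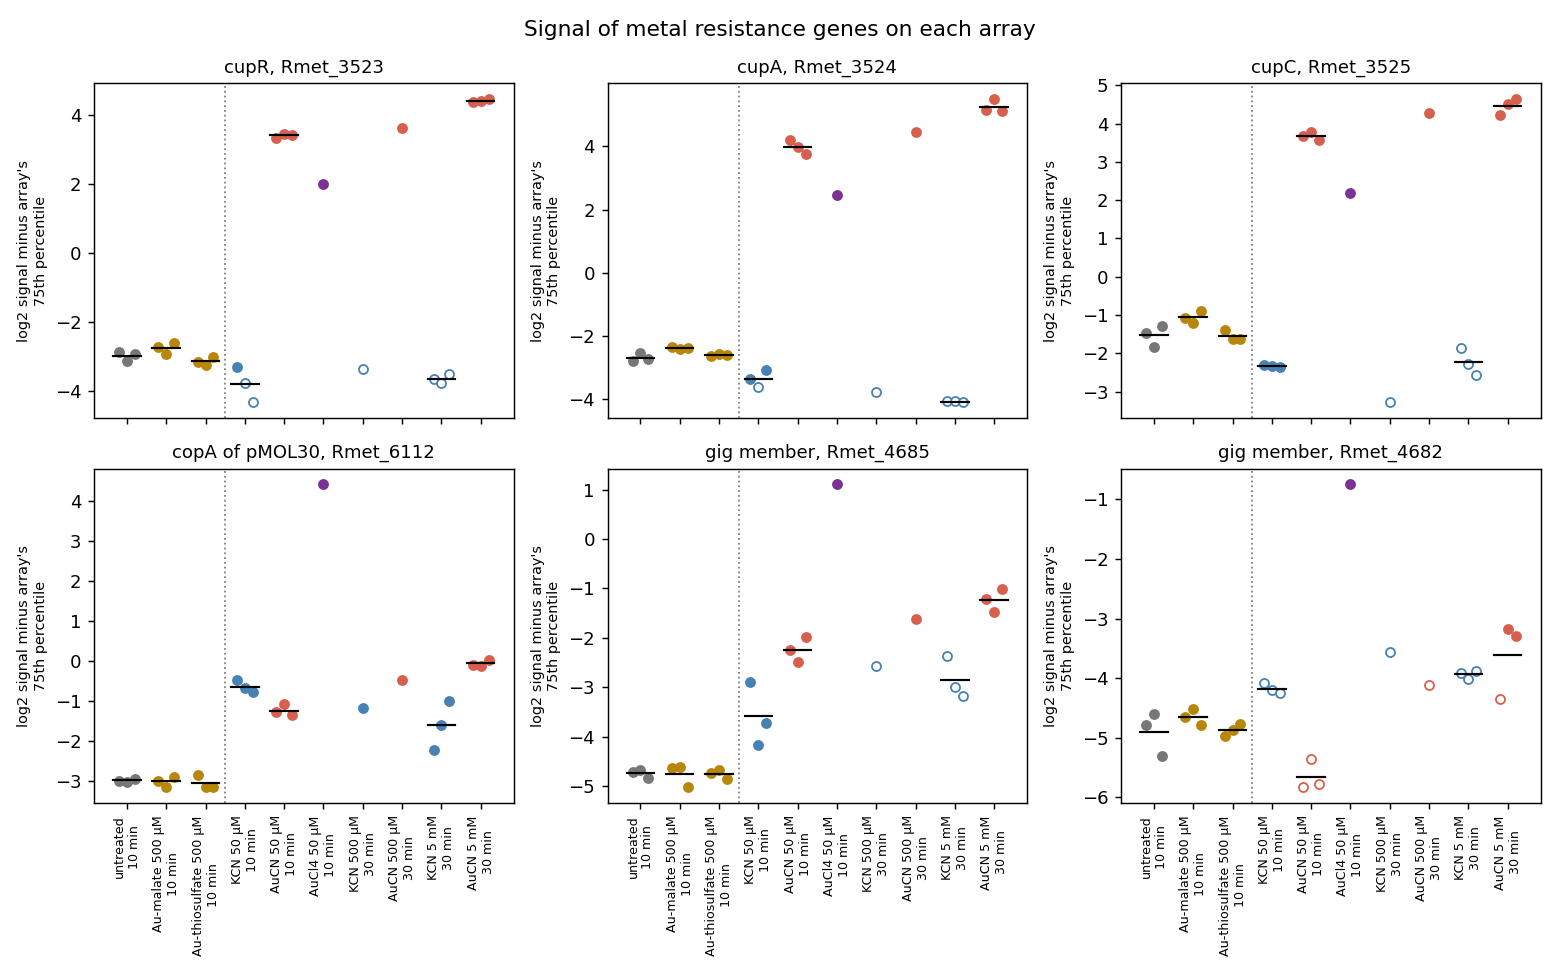
Log2 signal, relative to the 75th percentile of each array, of 6 metal-response genes on every array. Filled points are well above background, open points are not, bars are group means and the dotted line parts the 2 array series.

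The gene cupA (Rmet_3524) rose at least 158-fold (adjusted p = 1.0e-12), cupR (Rmet_3523) at least 131-fold and cupC (Rmet_3525) 64.2-fold (SE 0.17 on the log2 scale); cupA was well above background on 2 and cupR on 1 of the 3 KCN arrays. As a set the cup genes were higher with an adjusted p of 6.1e-08 (adjusted p = 0.0046 with an estimated correlation). The rise lay within a run of 6 neighbouring genes, Rmet_3521 to Rmet_3526. Rmet_4889 rose at least 587-fold and Rmet_4888 at least 19.8-fold, neither being well above background on any KCN array. Runs of risen genes also lay at Rmet_5599 to Rmet_5602 (median 31.4-fold), Rmet_6172 to Rmet_6178 (20.1-fold) and Rmet_4865 to Rmet_4869 (15.3-fold). The largest falls were those of Rmet_4958 (98.1-fold, log2 change -6.62, SE 0.16) and Rmet_4955 (91.7-fold, -6.52, SE 0.14), in the run Rmet_4953 to Rmet_4958 with a median fall of 82.4-fold. The runs Rmet_5231 to Rmet_5234 (30.3-fold), Rmet_1376 to Rmet_1379 (15.8-fold) and Rmet_2811 to Rmet_2816 (4.87-fold) also fell.

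Within the cop cluster of 19 genes, 7 rose and 4 fell, 5 adjusted over the list alone, and the set gave an adjusted p of 0.20. Rmet_6119 rose 10.1-fold (log2 change 3.34, SE 0.14) and Rmet_6118 9.34-fold (3.22, SE 0.16), and Rmet_6108 fell (-1.45, SE 0.18). For copA the change was -0.60 (SE 0.23, adjusted p = 0.068) and for copB 0.06 (SE 0.13, adjusted p = 0.77). Among the gig genes Rmet_4685 rose (1.35, SE 0.31) and Rmet_4683 fell (-0.68, SE 0.13), while Rmet_4682 was not well above background in either group, and the set gave an adjusted p of 0.73. All 4 measured cus genes rose (median 0.99, adjusted p = 0.034, or adjusted p = 0.24 with an estimated correlation). Among them Rmet_5033 rose by 1.74 (SE 0.46) and Rmet_5034 by 1.02 (SE 0.35). These SEs come from the joint fit, and the AuCN replicates spread more widely than the KCN ones. Their standard deviations were 1.42 against 0.054 for Rmet_5033, 0.997 against 0.188 for Rmet_5034 and 0.698 against 0.036 for Rmet_5031. For Rmet_5030 the AuCN spread was the smaller (0.042 against 0.259). The cus rise may therefore rest on part of the AuCN replicates. In the czc region, the efflux region for cobalt, zinc and cadmium, Rmet_5970 rose 7.45-fold (2.90, SE 0.35) and 2 genes fell, for an adjusted p of 0.86, a median of -0.16 and a mean of 0.09. In cop2 and sil 1 gene each fell, Rmet_5671 by a log2 change of -0.57 and Rmet_6133 by -0.61.

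Of the 6 heat shock and protease genes 4 rose, hslU 4.41-fold (log2 change 2.14, SE 0.17) and groES 4.16-fold (2.06, SE 0.14), and the set was higher by a median of 1.26 (adjusted p = 0.0023; adjusted p = 0.080 with an estimated correlation). The ribosomal protein genes were higher by a median of 0.89 (adjusted p = 3.6e-24; adjusted p = 0.080 with an estimated correlation). Among them rplW rose 4.03-fold (2.01, SE 0.17) and rplC by 1.77. In the flagellum list only fliF rose (1.06, SE 0.17). In the TCA cycle sdhA rose (0.58) and kgd (-0.80) and acnA (-0.45) were among 3 that fell, with 3 each way adjusted over the list alone. The TCA median was 0.12 and the mean -0.05, with the set test pointing down (adjusted p = 0.89). The iron-sulfur assembly genes hscA (2.86-fold, log2 change 1.51, SE 0.12) and hscB (2.82-fold, SE 0.12) rose, as did cysM of sulfate assimilation (0.66, SE 0.18), and atpC of ATP synthase fell (-0.41, SE 0.13). The phosphate transport genes pstA (-0.36, adjusted p = 0.32) and pstC (-0.48, adjusted p = 0.21) did not pass.

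Over all genes 1833 of 6047 changed (30.3%), 937 up and 896 down, of which 400 and 335 changed at least 2-fold, and 2413 had an unadjusted p under 0.05. With the arrays of slide 4 only, 2 of AuCN and 1 of KCN, 430 genes changed, 16 of them ribosomal protein genes. Scaled to the spike-in probes, the median of all genes was 0.16 in place of -0.10, and 1083 genes rose and 301 fell.

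At 5 mM and 30 min, AuCN again raised the cup genes over KCN, and here copA and copB rose too. Of 47 ribosomal protein genes, most of them higher with AuCN at the lower dose, 44 were lower here, as were 12 of 20 flagellum genes besides 3 dim in both groups. The KCN arrays of this pair had only 43.4% to 45.5% of probes well above background, so many folds are lower bounds. The comparison asked what gold adds to cyanide at a high dose, with 3 arrays in each group and the free cyanide again not given.

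The gene cupA rose at least 133-fold, cupC at least 76.6-fold and cupR at least 74.4-fold, since none was well above background with KCN. The median log2 change of the cup set was 8.07, or 6.26 with its members at their bounds (adjusted p = 0.00039; adjusted p = 0.049 with an estimated correlation). Rmet_4889 rose at least 1476-fold and Rmet_5594 288-fold (log2 change 8.17, SE 0.13). The largest falls were Rmet_R0049 at 131-fold (-7.03, SE 0.29) and Rmet_R0013 at 115-fold (-6.85, SE 0.29). In the cop cluster copA rose 2.91-fold (1.54, SE 0.23, adjusted p = 4.7e-05) and copB 2.10-fold (1.07, SE 0.13, adjusted p = 6.1e-06), with Rmet_6119 at least 10.4-fold and Rmet_6118 at least 6.45-fold higher. Of the cop genes 11 rose, 1 fell and 4 were dim in both groups, and the median was 0.85, or 0.03 with the dim members at their bounds. The set passed with an adjusted p of 0.034 (adjusted p = 0.15 with an estimated correlation), and gave 0.16 over genes well above background on every array and 0.063 scaled to the spike-in probes.

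**Figure D3:**
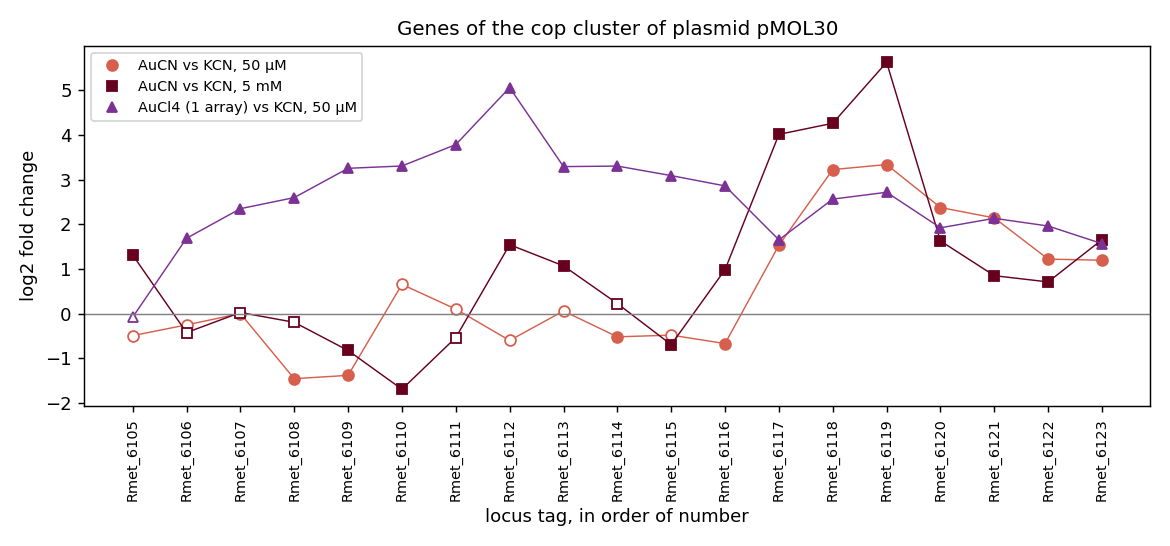
Log2 change of each measured gene from Rmet_6105 to Rmet_6123 in AuCN against KCN at 50 µM, in AuCN against KCN at 5 mM, and in the AuCl4 array against 50 µM KCN. Filled points passed the threshold; copA rose in the AuCl4 array by 5.06 and did not pass in AuCN at 50 µM.

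Among the gig genes Rmet_4685 rose at least 1.48-fold and Rmet_4683 fell (log2 change -0.84, SE 0.13), which scaling to the spike-in probes turned to 0.38. In the cus region Rmet_5030 rose at least 1.44-fold while Rmet_5034 (-1.05) and Rmet_5031 (-0.87) fell, both turned by the same scaling to 0.17 and 0.34; the cus median was -0.38 and the mean 0.14, with the set test pointing up (adjusted p = 0.96). In cop2, Rmet_5672 rose at least 1.31-fold and Rmet_5671 fell (-0.68, turned to 0.53). In sil, Rmet_6136 rose at least 1.65-fold and Rmet_6133 at least 1.93-fold. The czc region had 5 risen and 6 fallen genes besides 3 dim in both groups, a median of 0 at the bounds, Rmet_5970 at least 23.5-fold higher and Rmet_5980 lower by -1.77 (SE 0.35).

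The heat shock list was higher by a median of 1.97, or 1.67 at the bounds (adjusted p = 0.012; adjusted p = 0.15 with an estimated correlation), and gave 0.054 over genes well above background on every array. In it clpS rose at least 18.1-fold and groES 13.5-fold (3.76, SE 0.14), while groEL fell (-0.47, SE 0.19), a change that spike-in scaling turned to 0.75. The ribosomal protein genes were lower by a median of -1.84 (adjusted p = 3.0e-13; adjusted p = 0.15 with an estimated correlation), or -0.62 with 26 fallen and 6 risen when scaled to the spike-in probes, where the median of all genes was 1.11 in place of -0.11. In this list rpsJ fell by a log2 change of -3.46 (SE 0.16) and rplS 8.57-fold (-3.10, SE 0.16), while rpsT (1.56, SE 0.16) and rpsU (0.54, SE 0.12) rose. Flagellum genes were lower by a median of -2.14, or -1.53 at the bounds (adjusted p = 0.00014; adjusted p = 0.24 with an estimated correlation), with flgG at least 26.7-fold and flgE at least 13.8-fold lower and motB higher (0.78). The flagellum median was -0.92 scaled to the spike-in probes, and the set gave 0.41 over genes well above background on every array. The TCA cycle list did not pass (adjusted p = 0.052; adjusted p = 0.25 with an estimated correlation), with sucC (-2.83, SE 0.11) and sdhA (-2.08, SE 0.17) fallen and kgd0 risen (1.95, SE 0.11). The genes hscB (2.09), hscA (0.90) and cysM (1.39) rose and atpC fell (-2.70, SE 0.13).

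Over all genes 3852 of 6047 changed (63.7%), 1838 up and 2014 down, of which 1281 and 1185 changed at least 2-fold. Restricted to 2938 genes well above background on all 6 arrays, 2315 changed, 735 up and 1580 down. Scaled to the spike-in probes, 3912 rose and 453 fell. Across genes, the AuCN against KCN changes at 50 µM and at 5 mM had a Pearson r of 0.110 and a Spearman rho of -0.03; 390 genes rose at both doses against 285 expected by chance, and 259 fell at both against 298 expected. In opposite directions, 392 rose at 50 µM and fell at 5 mM (312 expected) and 381 fell at 50 µM and rose at 5 mM (272 expected).

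**Figure D4:**
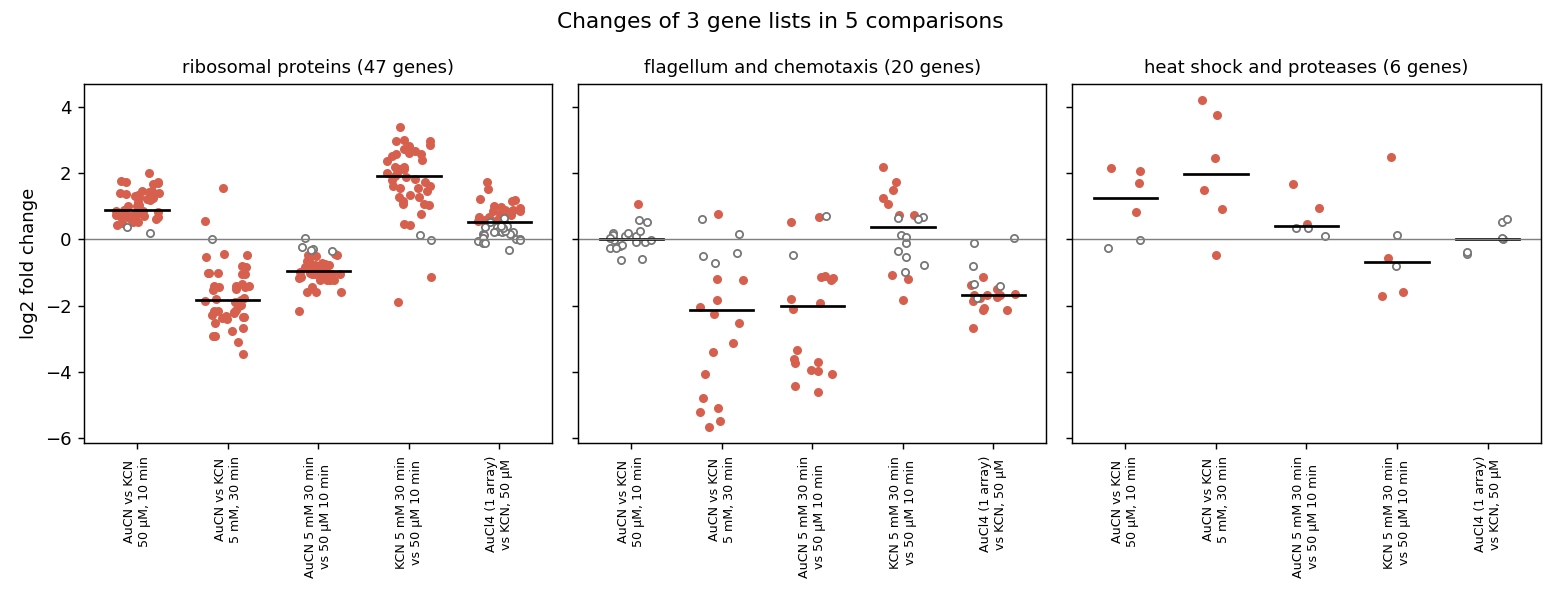
Log2 change of the ribosomal protein, flagellum and heat shock genes in AuCN against KCN at 50 µM and 5 mM, between doses of AuCN and of KCN, and in the AuCl4 array against KCN. Red points passed an adjusted p of 0.05, open points did not, and lines are medians; scaled to the spike-in probes, the ribosomal median between KCN doses is 0.01 and the flagellum median is -1.52.

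Between 50 µM for 10 min and 5 mM for 30 min of AuCN, flagellum and ribosomal protein genes fell. The cup genes rose a little further, except that cupC fell by -0.15 when scaled to the spike-in probes. Dose and time changed together, so the comparison cannot part them. Each group had 3 arrays. Flagellum genes were lower by a median of -2.03, or -1.26 at the bounds, with 16 fallen and 2 risen (adjusted p = 7.2e-07; adjusted p = 0.15 with an estimated correlation). Among them flgB fell 16.9-fold (-4.08, SE 0.25), flgD at least 9.66-fold and flgE at least 5.83-fold; over genes well above background on every array, 4 fell, 2 rose and the set gave 0.16. The risen motB (0.68) and flgK (0.53) turned to -0.25 and -0.41 scaled to the spike-in probes. Ribosomal protein genes were lower by a median of -0.95 with 42 fallen, 43 adjusted over the list alone (adjusted p = 9.1e-14; adjusted p = 0.15 with an estimated correlation), and rpsU fell by -2.17 (SE 0.12). The genes cupA, cupR and cupC rose by 1.28 (SE 0.16), 1.01 (SE 0.20) and 0.79 (SE 0.17), a set median of 0.07 when scaled to the spike-in probes, with the set at an adjusted p of 0.065.

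In the cop cluster 8 genes rose and 1 fell, with copA at 1.17 (SE 0.23), copB at 1.29 (SE 0.13) and Rmet_6121 at -1.88 (SE 0.23), but scaled to the spike-in probes none rose and 9 fell. The gig genes Rmet_4683 (1.21, SE 0.13), Rmet_4685 (1.01, SE 0.31) and Rmet_4682 (at least 1.31-fold) rose. Of the heat shock list 3 genes rose, clpS by 1.68 (SE 0.16) and clpX by 0.94 (SE 0.35), for an adjusted p of 0.14. In the TCA cycle acnA rose (1.36) and sdhA (-1.37) and sucC (-1.14) were among 4 that fell. In cop2 and sil 2 genes each rose, in cus Rmet_5030 fell (-0.82), and in czc 3 rose and 1 fell. Rmet_5594 rose 64.1-fold (SE 0.13) and Rmet_5580 64.0-fold (SE 0.22), while Rmet_2753 fell at least 7.32-fold and Rmet_3963 at least 16.2-fold. Over all genes 3160 of 6047 changed, 1637 up and 1523 down. With the arrays of slide 4 only 1314 changed, and scaled to the spike-in probes the median of all genes was -0.86, with 247 risen and 3492 fallen.

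KCN alone showed the opposite for ribosomal protein genes between the same doses and times. Of 47, 43 rose and 2 fell, but 15 rose and 14 fell when scaled to the spike-in probes, on the 5 mM KCN arrays with low signal. Each group had 3 arrays. The ribosomal median was 1.91 (adjusted p = 7.6e-15; adjusted p = 0.48 with an estimated correlation), but 0.01 when scaled to the spike-in probes, where the median of all genes was -1.84 in place of 0.06. Among them rpsS rose by 3.40 (SE 0.12) and rplV 8.08-fold (3.01, SE 0.14), and rpsU (-1.88, SE 0.12) and rpsT (-1.13, SE 0.16) fell. Of the flagellum genes 7 rose and 3 fell (adjusted p = 0.67), fliF by 2.17 and flgB by 1.74, the latter -0.16 and the list median -1.52 scaled to the spike-in probes. In the heat shock list groEL rose 5.65-fold (SE 0.19) and clpS (at least 3.22-fold) and groES (-1.59, SE 0.14) fell. In the TCA cycle sucC (1.96) and acnA (1.56) were among 5 that rose, acnA turning to -0.34 with spike-in scaling, and kgd0 fell (-2.22).

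None of the cup genes was well above background with 5 mM KCN, so no change is given for them. The gene copA fell by a log2 change of -0.97 (SE 0.23, adjusted p = 0.0023) and copB did not pass (0.28, adjusted p = 0.075), and in the cop cluster 6 genes fell, 5 adjusted over the list alone, and 1 was dim in both groups. Of the gig genes Rmet_4683 rose (1.37) and turned to -0.52 with spike-in scaling, and Rmet_4685 was not well above background with 5 mM KCN. In cus 2 genes rose and 1 fell, in cop2 3 and 1, in sil 0 and 2, and in czc 6 and 5. Rmet_4564 rose 164-fold (7.36, SE 0.26) and Rmet_R0049 by 6.74 (SE 0.29), while Rmet_4958 fell at least 82.8-fold and Rmet_4957 at least 56.4-fold. Over all genes 4035 of 6047 changed, 2030 up and 2005 down, and 2395 of 2979 genes well above background on every array compared changed. Scaled to the spike-in probes 96 rose and 5111 fell. Changes between doses of AuCN and of KCN had a Pearson r of 0.012 and a Spearman rho of 0.10 across genes; 750 genes rose in both against 550 expected by chance, and 568 fell in both against 505 expected. In opposite directions, 485 rose with AuCN and fell with KCN (543 expected) and 559 fell with AuCN and rose with KCN (511 expected).

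The AuCN against KCN difference itself depended on the dose and time, by a test of the interaction over all 4 groups. Ribosomal protein and flagellum genes had lower differences at 5 mM, and copA and copB higher ones. The ribosomal median interaction was -2.80 (adjusted p = 8.6e-23; adjusted p = 0.19 with an estimated correlation), with 45 of 47 genes lower and rpsS (-4.59, SE 0.17) and rplV (-4.26, SE 0.20) lowest, and it was -1.84 scaled to the spike-in probes. The flagellum median was -2.34 (adjusted p = 9.3e-05; adjusted p = 0.31 with an estimated correlation), with flgB at -5.82 (SE 0.36), and the set gave 0.40 over genes well above background on every array. For copA the interaction was 2.14 (SE 0.33) and for copB 1.01 (SE 0.19). No interaction is given for the cup genes, which were not well above background with 5 mM KCN. The cop cluster had 9 genes higher and 2 lower, although 11 of its 19 members were dim in at least 1 group at 5 mM, and the heat shock list 4 and 1, with groEL at -2.17. Of 6047 genes 3173 passed, 1674 higher and 1499 lower. The count was 1954 of 2931 genes well above background on every array compared and 1807 with the arrays of slide 4 only.

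The AuCl4 array showed the copper-resistance genes high together. Compared with 50 µM KCN at 10 min, 18 of 19 cop genes, all 3 cup genes, all 3 measured gig genes and 5 of 6 cop2 genes rose, while 14 of 20 flagellum genes fell. AuCl4 had 1 array, which the test assumed to vary like the other groups, so its p values and counts describe this array and rest on the spread of other treatments. Its array series held no untreated cells, so the KCN group served as the reference. The gene copA rose 33.3-fold (log2 change 5.06, SE 0.33, adjusted p = 1.4e-07) and copB 9.78-fold (3.29, SE 0.19), and the cop median was 2.60 (adjusted p = 1.4e-14; adjusted p = 0.00026 with an estimated correlation). The genes cupA and cupR rose at least 55.5- and 48.7-fold and cupC 22.8-fold (set adjusted p = 3.0e-07; adjusted p = 0.0035 with an estimated correlation). Of the gig genes Rmet_4685 rose 26.1-fold (4.71, SE 0.44), Rmet_4682 at least 8.83-fold and Rmet_4683 by 0.99 (set adjusted p = 0.00065; adjusted p = 0.019 with an estimated correlation). Rmet_4684, left out by the filter, was well above background on the AuCl4 array (log2 signal 1.56) and on no AuCN or KCN array. In cop2 Rmet_5672 rose by 2.87 (SE 0.22), and all 6 passed adjusted over the list alone (set adjusted p = 0.00016; adjusted p = 0.013 with an estimated correlation).

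Flagellum genes were lower by a median of -1.68 (adjusted p = 4.6e-10; adjusted p = 0.053 with an estimated correlation), with flgL at -2.66 (SE 0.49) and fliG at least 4.40-fold lower. Of the ribosomal protein genes 22 rose, rplN by 1.72 (SE 0.27), and the median was 0.53 (adjusted p = 1.1e-05; adjusted p = 0.38 with an estimated correlation). No heat shock gene passed (adjusted p = 0.92), 1 gene each rose in cus and sil, 3 rose and 3 fell in czc, and kgd fell by -0.63, turning to 0.04 with spike-in scaling. Rmet_4889 rose at least 96.5-fold and Rmet_3620 104-fold (6.69, SE 0.22), while Rmet_4955 fell 233-fold (-7.87, SE 0.20) and Rmet_4958 201-fold (-7.65, SE 0.22). Over all genes 1386 of 6047 changed, 862 up and 524 down, a balance that centring on the median turned to 622 up and 827 down. The count was 2151 in one fit over all 24 arrays, 447 with the arrays of slide 4 only and 2319 scaled to the spike-in probes, with 2166 risen and 153 fallen and a median of all genes of 0.78 in place of 0.12.

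Against AuCN at the same dose and time, the AuCl4 array had higher copA, copB and gig signals and lower cup signals. The gene copA was 50.5-fold higher (5.66, SE 0.33) and copB higher by 3.23 (SE 0.19), while cupR, cupA and cupC were lower by -1.42, -1.51 (SE 0.23) and -1.49 (SE 0.24). The cop cluster had 11 genes higher and 2 lower, with Rmet_6118 (-0.66) and Rmet_6119 (-0.62) the lower pair (set adjusted p = 3.4e-06; adjusted p = 0.0077 with an estimated correlation). Of the gig genes Rmet_4682 was at least 9.58-fold higher, Rmet_4685 higher by 3.36 (SE 0.44) and Rmet_4683 by 1.67 (set adjusted p = 0.00030; adjusted p = 0.018 with an estimated correlation). All 6 cop2 genes were higher (adjusted p = 9.2e-05; adjusted p = 0.015 with an estimated correlation), as was sil (adjusted p = 0.037; adjusted p = 0.25 with an estimated correlation), and cup was lower as a set (adjusted p = 0.00063; adjusted p = 0.020 with an estimated correlation). Heat shock genes were lower by a median of -1.17 (adjusted p = 0.00040; adjusted p = 0.034 with an estimated correlation), groEL by -1.68 (SE 0.27) and groES by -1.53 (SE 0.19). Flagellum genes were lower in 17 of 20 (adjusted p = 3.5e-10; adjusted p = 0.040 with an estimated correlation), and ribosomal protein genes in 22 with 2 higher (median -0.54, adjusted p = 7.3e-09; adjusted p = 0.17 with an estimated correlation). Rmet_3620 was 130-fold higher (7.02, SE 0.22), and Rmet_5793 was lower by -4.37 (SE 0.33). Over all genes 1653 of 6047 passed, 977 higher and 676 lower, and 1007 with the arrays of slide 4 only. Centring on the median turned the balance, with 651 higher and 1088 lower.

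At 500 µM and 30 min, AuCN and KCN had 1 array each, so values carry no test. The cup genes were well above background on the AuCN array and not on the KCN array, so no fold is given. Of 3090 genes well above background on both arrays, 150 were at least 4-fold higher with AuCN and 135 at least 4-fold lower, and their median difference was -0.33. The heat shock median of 2.46 (5 of 6 members well above background on both arrays) lay above 99.96% of 10000 random gene lists of the same size, matched on signal. The TCA cycle median of 1.89 (5 of 7 members) lay above 99.64% and the ribosomal median of 0.47 (46 of 47) above 97.66%. The cus (0.18, 3 of 4) and cop2 (-0.83, 5 of 6) medians lay above 62.6% and 5.37%. In the cop, cup, gig, sil, czc and flagellum lists under 50% of members were well above background on both arrays, so no median is given. The gene copA differed by 0.69 and copB by 0.52. Rmet_5599 (6.13) and Rmet_6173 (5.97) were higher with AuCN, and Rmet_R0049 (-6.01) and Rmet_4956 (-5.96) lower.

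Against untreated cells, the cup genes stood higher with AuCN and not with KCN, while other regions were high with both. These comparisons cross the 2 array series, so treatment cannot be told apart from array design, slide, scan and scanner software, and at 5 mM dose and time differ too. The genes cupR, cupA and cupC were higher by 6.40, 6.67 and 5.21 with 50 µM AuCN and 5 mM AuCN gave 7.41 and 7.94 for cupR and cupA and 63.9-fold for cupC. With 50 µM KCN cupR and cupA were at least 1.55- and 1.56-fold lower and cupC lower by -0.80, and with 5 mM KCN none was well above background, so no change is given. As a set cup was higher with AuCN at 50 µM (adjusted p = 0.00051; adjusted p = 0.012 with an estimated correlation) and 5 mM (adjusted p = 0.0020; adjusted p = 0.039 with an estimated correlation). The gene copA was higher in all 4 groups, by 1.74 and 2.92 with AuCN and by 2.34 and 1.37 with KCN, and copB by 2.07, 3.36, 2.01 and 2.29. The cop set passed with AuCN at 50 µM (adjusted p = 0.0019; adjusted p = 0.032 with an estimated correlation) and 5 mM (adjusted p = 0.016; adjusted p = 0.096 with an estimated correlation). Rmet_5978 of czc was higher by 6.25 to 8.36 and Rmet_5671 of cop2 by at least 147-fold in each of the 4 groups.

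The czc set was higher with AuCN at 50 µM (adjusted p = 0.010; adjusted p = 0.032 with an estimated correlation), with AuCN at 5 mM (adjusted p = 0.033; adjusted p = 0.096 with an estimated correlation) and with KCN at 50 µM (adjusted p = 0.043; adjusted p = 0.14 with an estimated correlation). With AuCN at 50 µM, cus (adjusted p = 0.022; adjusted p = 0.22 with an estimated correlation), heat shock (adjusted p = 0.032; adjusted p = 0.14 with an estimated correlation) and cop2 (adjusted p = 0.043; adjusted p = 0.14 with an estimated correlation) were higher. The genes groES and groEL were higher by 2.73 and 2.52 at 50 µM and by 2.84 and 2.85 at 5 mM. At 5 mM AuCN, heat shock (adjusted p = 0.016; adjusted p = 0.096 with an estimated correlation) and gig (adjusted p = 0.029; adjusted p = 0.096 with an estimated correlation) were higher. There flagellum genes were lower by a median of -3.52, or -2.93 at the bounds, with 18 fallen and 1 risen (adjusted p = 7.6e-05, or 0.15 with an estimated correlation). Lower there too were ribosomal protein genes (adjusted p = 0.0014, or 0.40 with an estimated correlation). Ribosomal protein genes were lower with 50 µM KCN (adjusted p = 2.5e-05; adjusted p = 0.45 with an estimated correlation) and higher with 5 mM KCN (adjusted p = 0.031; adjusted p = 0.72 with an estimated correlation), on the arrays with low signal. The ribosomal median with 50 µM AuCN was -0.26, with 12 risen and 21 fallen. With 50 µM KCN it was -1.12, with 6 risen and 38 fallen. Of 6542 genes, 4743, 4771, 5112 and 5251 passed with 50 µM AuCN, 50 µM KCN, 5 mM AuCN and 5 mM KCN. For 5 mM KCN 2527 of 2931 genes well above background on every array compared passed.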

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

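Of the tests in this part, those on labelling, dim spots, falling transcripts and the value table were chosen after the result was seen. Scaling to the spike-in probes was too, while the splits and the choice among scalings were planned.

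The difference between AuCN and KCN at 5 mM and 30 min departed from that at 50 µM and 10 min for 3173 of 6047 genes, by a test of the interaction. Of 100 splits of the samples only the real 1 gave as many, and the highest of the others gave 2523. Those splits mix treatments and so hold treatment differences of their own, so they cannot tell what chance alone would give. The ribosomal protein genes had a median interaction of -2.80 on the log2 scale.

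In data outside the gene comparisons, 764 of 2801 intergenic probes (27.3%) differed between AuCN and KCN at 50 µM, 363 higher and 401 lower. The share was near that of genes in the same comparison, 30.3% (1833 of 6047). Against untreated cells the intergenic counts were 26 of 3122 with Au-malate and 0 with Au-thiosulfate (limma), where 304 had an unadjusted p under 0.05. With Au-malate the shares were 0.83% of intergenic probes and 0.96% of genes. No explanation for the intergenic signal was tested.

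The first pattern weighed was the low gene signal with 5 mM KCN. The 75th percentile of signal was 0.229 of that with 50 µM KCN. Weaker labelling or hybridisation of these arrays would lower the spike-in probes alike, but their ratio was 0.835, which argues against it as the whole cause. This ratio covers only faults that dim spike-in and sample RNA alike. The amount of sample RNA on each array was not tested. The many changed genes at 5 mM might also come from dim spots scaled up to the same percentile. Of the 2938 genes well above background on all 6 arrays 78.8% changed, 735 up and 1580 down, which decides nothing because scaling also shifts genes that stay bright. With each array centred on the median of these genes 73.1% changed, 924 up and 1224 down, which argues against dim spots and a common shift of the bright genes as the whole cause. A smaller share of messenger RNA in total RNA with 5 mM KCN, by death or arrest of cells or by RNA breakdown, stays open. The signal of Rmet_R0070 and Rmet_R0073, taken as ribosomal RNA, had a ratio of 0.999, but probes this bright (463351 units with 5 mM KCN) may be near the limit of binding, so this does not decide. The 500 µM KCN array, which received a lower dose for the same 30 min, had a 75th percentile of 19.0 and 42.0% of probes well above background.

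The second pattern was the opposite change of the ribosomal protein genes in AuCN against KCN, up at 50 µM and down at 5 mM. The choice among percentile, median, quantile and normexp scalings was argued against, since the highest median at 5 mM over these scalings was -1.28. If most other transcripts fell with 5 mM KCN, scaling would have raised the ribosomal protein genes there. Scaled to the spike-in probes the median at 5 mM was -0.62, between the bounds that would have decided, so a fall of most other transcripts cannot be told apart from a change of the ribosomal protein genes. A response of these genes to gold or to cyanide is a hypothesis that stays open, as does the time of exposure, which differed between the doses.

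The third pattern was the authors' value table in the second series. In 18 windows of 200 lines (3600 lines) its values matched the scanner files with a median r of 0.985, while in 30 windows (6000 lines) the median r was 0.370. Wrong probe names in the scanner files were argued against: over the parting lines the scanner values correlated with the first series better than the table did by 0.342 (0.791 against 0.449). Whether lines were out of place in the table cannot be told: the table correlated with the first series by 0.846 over the matching lines and less by 0.396 over the parting ones, but in 1 parting window 8 lines around the cup genes held the AuCN against KCN differences in place (cupR 6.64, against 7.21 in the scanner files). No biological explanation was tested for this pattern. These correlations are across genes, which are not independent replicates.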

How the results depend on the processing

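The tests on genes well above background on every array, without the high-dose KCN arrays, by slide and with spike-in scaling were chosen after the data had been seen; the other alternatives were planned.

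Of the counts of changed genes and of passing list tests under the alternatives, 211 stayed within 1.5 times the reported count and 25 did not. Only totals were compared here, so a shift between risen and fallen genes could pass as stable. Scaling to the spike-in probes made such shifts, with the numbers given in Results. It moved the balance toward rises for AuCN against KCN at both doses. Between the doses of AuCN and between those of KCN it moved the balance toward falls. The values of named genes were counted together with the tests of the cup and gig lists. Of these, 8900 kept their side of the threshold, 544 lost the call, 19 gained it and 28 reversed. A change of direction was counted only for values that had passed. For the other gene lists the numbers were 312 kept, 45 lost and 3 gained. Unless stated, the cause of a change was not tested.

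With a fit over all 24 arrays, Au-malate against untreated gave 31 genes, Au-malate against Au-thiosulfate 35 and AuCl4 against KCN 2151. For Au-malate against Au-thiosulfate a slide block gave 33 and a replicate block 117. Among genes well above background on every array compared, which were fewer, AuCN against KCN at 5 mM gave 2315, KCN 5 mM against 50 µM 2395, the interaction 1954 and KCN 5 mM against untreated 2527. With slide 4 only, which left 1 or 2 arrays in each group, AuCN against KCN at 50 µM gave 430, AuCN 5 mM against 50 µM 1314, the interaction 1807, AuCl4 against KCN 447 and AuCl4 against AuCN 1007. Scaled to the spike-in probes, AuCl4 against KCN gave 2319. With an estimated correlation, 16 of 154 list tests passed in place of 57; quantile normalization gave 55, and a replicate block 41 of 132, where 43 of the same 132 had passed.

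Leaving out each replicate gave 29 to 52 genes for Au-malate, 0 to 7 for Au-thiosulfate and 26 to 72 between them. It gave 1412 to 1556 for AuCN against KCN at 50 µM, 3598 to 3855 at 5 mM, 2703 to 2869 between AuCN doses, 3688 to 3992 between KCN doses and 2934 to 3334 for the interaction. It gave 1113 to 1197 for AuCl4 against KCN and 1365 to 1479 against AuCN. Against untreated cells the ranges were 4478 to 4541 (50 µM AuCN), 4490 to 4562 (50 µM KCN), 4912 to 5002 (5 mM AuCN) and 5040 to 5188 (5 mM KCN).

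The reversed genes were these. By normexp, Rmet_6109 at 5 mM AuCN against KCN (0.082), where it was well above background in neither group. By quantile, Rmet_4682 in 5 mM KCN against untreated (-0.44). With slide 4 only, Rmet_5979 in the interaction (0.14). Spike-in scaling, which shifts all genes of an array together, reversed 25. At 5 mM AuCN against KCN these were Rmet_6109 (0.39, dim in both groups), Rmet_4683 (0.38), Rmet_5034 (0.17), Rmet_5031 (0.34), Rmet_5671 (0.53) and groEL (0.75). Between AuCN doses they were Rmet_5669 (-0.31), hscB (-0.43), motB (-0.25), flgK (-0.41) and Rmet_3525 (-0.15). Between KCN doses they were Rmet_6110 (-0.42, dim in both groups), Rmet_4683 (-0.52), Rmet_4685 (-1.15), Rmet_5031 (-0.42), Rmet_5670 (-0.072), Rmet_5671 (-0.51), Rmet_5980 (-0.17), Rmet_5978 (-0.24), hscA (-1.06), atpC (-0.89), flgB (-0.16) and acnA (-0.34). The others were hscA in the interaction (0.34) and kgd in AuCl4 against KCN (0.037).

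Centring on the median turned the balance for AuCl4, with 622 risen and 827 fallen against KCN and 651 and 1088 against AuCN. The value table was not run for the second series, a slide block not across the series, whose slides are nested in them, and a replicate block not for the lone array. Signal over background limits the 5 mM KCN comparisons, where 43.4% to 45.5% of probes were well above background.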

Other observations

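In this part the tests on neighbouring genes, on the genes lowered by Au-malate and on AuCl4 were chosen after the result was seen; the splits of the samples and the detection of the cup genes were planned.

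With 3 arrays against 3 there are 10 splits of the samples, too few for a share under 0.05. The real split of Au-malate against untreated gave 62 genes and the highest other 21. For Au-thiosulfate the real split gave 0 genes and the highest other 2, so all 10 gave as many. Au-malate against Au-thiosulfate gave 69 genes and the highest other 0. AuCN against KCN gave 1833 at 50 µM and 3852 at 5 mM, the doses of AuCN 3160 and those of KCN 4035, with 0 for the highest other in each. Against untreated cells the real splits gave 4743 (50 µM AuCN), 4771 (50 µM KCN), 5112 (5 mM AuCN) and 5251 (5 mM KCN), and the highest others 0, 0, 1 and 0. In each of these except Au-thiosulfate, 1 of 10 splits gave as many, the real one. The other splits mix the groups compared, so differences between those groups widen the spread and can bring the count to 0. They cannot tell what chance alone would give.

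That no cup gene passed with Au-malate or Au-thiosulfate might have come from a lack of detection. Against cup genes below detection in the first array series stands that 3 of 3 cup genes were well above background on all 3 untreated arrays.

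Genes with at least 2-fold higher signal in AuCN than KCN at 50 µM lay next to each other by locus tag: of the 400 such genes 315 had a 4-digit locus tag, and 173 of these had a neighbour in the set (54.9%), against a median of 32 and at most 60 in 1000 random draws. Of 314 lower genes with such a tag 186 had one, against at most 53. This is in line with joint transcription of neighbouring genes, a hypothesis that these arrays do not test further.

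Of the 30 genes that fell with Au-malate, 21 were lower in AuCN than KCN at 50 µM and none was higher, while random lists matched on signal had at most 14. Without Rmet_2811 to Rmet_2817, 14 of 23 were lower, against at most 13. Both gold complexes may lower shared genes, a hypothesis found on the same data. The random lists drew genes singly, while neighbouring genes changed together, so their spread may be too narrow. Of the genes that rose with Au-malate, 7 were higher and 8 lower in AuCN than KCN at 50 µM (5.00 and 4.76 expected by chance). Across 5973 genes the Au-malate and AuCN changes had a Pearson r of 0.039 and a Spearman rho of -0.155. At 5 mM the direction turned: 20 of the 30 were higher in AuCN than in KCN and 2 lower.

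Outside the fixed lists 77 genes were at least 4-fold higher in AuCN than KCN at 50 µM, with a median log2 change of 2.95. In the AuCl4 array their median was 1.44 over KCN, where 59 passed as higher, but -1.72 against AuCN, where 62 passed as lower. Because these genes were picked for high values on the same AuCN arrays and AuCl4 had 1 array, this cannot tell whether AuCl4 raised them as AuCN did.

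The 2 comparisons of gold complexes with untreated cells shared the untreated arrays. Their changes correlated across genes by 0.237, below the 0.499 that simulated data without any effect gave from the shared arrays alone. Among genes with 2 probes, 18 of 3162 had probes more than a log2 change of 0.5 apart from 0 in opposite directions for AuCN against KCN at 50 µM, and 0 of the 879 changed genes with 2 probes did. Between KCN doses these numbers were 27 of 3162 and 2 of 1912. Genes were called on the mean of their probes, which makes such calls unlikely, so low numbers among changed genes say little. In the value table the 9 columns of the first series each matched another replicate of the same group best, with r of 0.998 to 0.999 across genes against 0.982 to 0.995 for the replicate of the same number.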
